A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

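RNA sequencing libraries came from Saccharomyces cerevisiae BY4741, a haploid laboratory strain of mating type a derived from S288C. Cultures grew at 30 °C in YPD, a rich medium of 2% glucose, 2% peptone and 1% yeast extract. The labels name 3 libraries of a SUL1 knockout and 2 of the wild type, each a biological replicate by its title, and the group of every library was taken from its genotype or title label. A further wild-type replicate that the design text mentions was not analysed here. The titles give an optical density at 600 nm of 0.6 for the knockout libraries only.

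The deposited tables hold FPKM per gene and library (fragments per kilobase of transcript, scaled to the fragments of the library), per the file headers, one table per strain. Each column was scaled on its own, so nothing in the tables sets the libraries to a common level. Per the submitters' processing notes, the tools were HISAT2 2.1.0, Bowtie2, RSEM 1.3.1 and DESeq2 1.4.5 with genome build R64. The notes give no role for any of them, and the annotation, read length and strand setting are not given in the sources used here. FPKM divides by gene length, so any difference between libraries in how well long transcripts are covered remains in the values.

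Both tables list 5886 genes. Of their gene identifiers, 5883 matched the R64 reference annotation, from which chromosome positions and coding lengths were taken, and 3 did not match. Symbols of 2 genes had been turned into calendar dates and were restored through the gene identifier. The gene models hold no untranslated regions, so lengths here are coding lengths. All 5 per-sample columns were used.

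No counts were used, so depth was estimated from the steps between low FPKM values. In genes of 250 to 1200 bp with values up to 1.5 FPKM, the number of fragments per library was found for which values became whole multiples of 1 fragment. Between 88.9% and 95.3% of 63 to 85 values per library then lay within 0.15 of a whole number, where an arbitrary depth gives 30%. The estimates were 24400000, 24250000 and 24600000 fragments for knockout replicates 1, 2 and 3, and 24450000 and 22550000 for wild-type replicates 1 and 2. On simulated data of 3 known depths the estimate was off by at most 0.208%. These depths served only to give a precision and entered no test.

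The design fixed before the data were examined was written for counts, with limma on log2 values as the fallback for normalized units. The FPKM were therefore tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trended prior variance and robust empirical Bayes moderation. A fold change on this scale understates the change of low genes. Genes with a mean of at least 1 FPKM over all 5 libraries entered, 5712 in number, and 174 were left out. The model held the genotype alone, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Adjusted p-values given for genes are from this limma test throughout. Tables were joined and drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

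The procedure was tested on simulated data, 5 simulations of this comparison over 5712 genes, with known changes spiked in. It recovered 68.8% of genes changed 1.5-fold, 92% of those changed 2-fold, 98.8% of those changed 4-fold and 99.6% of those changed 8-fold, with 75 false calls in total. Over the 5 simulations 250 genes were changed at each fold. With as few calls as the 15 of the real comparison the adjustment for multiple tests is stricter, so these shares may overstate what it can find. The simulation drew each gene's spread independently and does not model shifts shared by many genes of a library.

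The genes named were set by a rule written before the data were examined. SUL1 comes first. Next are up to 10 genes per direction with the largest log2 fold change among those past the threshold, with a mean of at least 10 FPKM and no overlap between the groups' libraries. From each fixed gene list come up to 3 members past the threshold or, failing that, the 2 members with the largest change. Preset genes included SUL2, MSN2, MSN4, TPK2, TPK3, BCY1, HSP12, CTT1, TPS1, GSY2, ATG8, HIS3, LEU2, MET17 and URA3, and not every gene that the rule selects is given. Any other gene named was chosen after its values were seen.

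In all, 27 gene lists were fixed from general knowledge of yeast genes. They cover the Msn2/Msn4 stress response, trehalose and glycogen, Hsf1 chaperones, ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, translation factors, and sulfate and methionine metabolism. They also cover phosphate, cAMP-PKA signalling, autophagy, glycolysis, glucose-repressed genes, respiration, amino acid biosynthesis, Yap1 targets, iron, the proteasome, histones and lifespan regulators. The rest hold mating-type a, mating-type alpha, haploid-specific and meiosis genes, stationary-phase markers, the auxotrophy loci of the strain and the neighbours of SUL1. The 26 lists with at least 3 tested genes were tested with camera of limma, which compares a list with all other genes, with a preset correlation of 0.01 between genes. Camera with a correlation estimated per list, and fry, a rotation test of the list by itself, were the alternatives. A count adjusted over the list alone applies the Benjamini-Hochberg method to the members of 1 list.

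Alternatives fixed beforehand were leaving out each library in turn, the replicate number as a block, another pseudocount, no filter, a stricter filter and a minimum fold change. Added after the data had been seen were median-of-ratios scaling, equal FPKM sums, library weights and removal of a length trend. For the last, a lowess curve (span 0.3) of each library's deviation from the gene means on log2 coding length was subtracted. Alternatives that need counts were not run.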

Results

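Messenger RNA was sequenced from yeast that lack SUL1, a high-affinity sulfate transporter of the plasma membrane, and from their wild-type parent BY4741. The series describes the cells as exponential, and an optical density is given for the knockout only. The comparison addresses how loss of SUL1 extends replicative lifespan, the number of daughters a mother cell produces, and whether protein kinase A (PKA) signalling is involved. There were 3 knockout and 2 wild-type libraries. Estimated depth was 24250000 to 24600000 fragments in the knockout and 22550000 to 24450000 in the wild type. The sums of FPKM ranged from 1837934 to 1947861 in the knockout and from 1732634 to 1808700 in the wild type. The 10 most abundant genes took 12.5% to 13.5% of these sums.

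SUL1 (YBR294W) lies on chromosome II at 789235 to 791814 of build R64, on the forward strand, with a single coding exon of 2580 bp. It was listed at 0 FPKM in knockout replicates 1, 2 and 3. The wild-type replicates had 8.28 and 9.78 FPKM, a mean of 9.03 ± 1.06 (SD, n = 2), which at the estimated depths is about 494 and 537 fragments. A gene of this length with 0 fragments could have had up to 0.0507 FPKM in these libraries, the worth of 3 fragments, and this limit covers counting error only. The difference passed the test (limma, adjusted p = 0.00395), though not without wild-type replicate 1 or 2 (adjusted p = 0.0872 and 0.119). The transcript level followed the genotype label in all 5 libraries. MET17, which BY4741 also lacks, was listed at 0 in all 5 libraries. HIS3, of which this strain carries a deletion allele, read 135 ± 5.44 FPKM in the knockout (SD, n = 3) and 142 ± 6.02 in the wild type (SD, n = 2), without a call. LEU2 and URA3 were not analysed here. The other sulfate permease, SUL2, differed by less than the spread between replicates, at 9.69 ± 1.25 FPKM in the knockout and 10.1 ± 1.80 in the wild type (log2 fold change -0.05 ± 0.17 SE, limma, adjusted p = 0.883).

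Loss of SUL1 was accompanied by higher transcript levels of 2 genes tied to stress and stationary phase. SPG4, needed for survival of high temperature in stationary phase, rose from 9.20 ± 1.79 FPKM in the wild type (SD, n = 2) to 41.2 ± 9.51 in the knockout (SD, n = 3), a log2 fold change of 2.03 ± 0.22 (SE, limma, adjusted p = 0.0316). HSP26, a small heat-shock chaperone, rose from 86.0 ± 12.1 to 250 ± 35.8 FPKM (1.53 ± 0.14, adjusted p = 0.0164). Smaller increases were found for NQM1, a transaldolase induced at the diauxic shift (1.10 ± 0.12, adjusted p = 0.0257), and RTN2, a reticulon of the endoplasmic reticulum (0.69 ± 0.09, adjusted p = 0.0492). GPG1, a proposed gamma subunit of the glucose-sensing G protein that acts upstream of PKA, rose from 119 ± 2.72 to 253 ± 39.6 FPKM (1.07 ± 0.13, adjusted p = 0.0349). TIR1, a cell wall mannoprotein, rose by 0.67 ± 0.09, and the uncharacterised reading frame YGR240C-A by 1.03 ± 0.13 (adjusted p = 0.0349 for both). MTC7, whose function is unknown, fell from 28.0 ± 5.39 to 10.8 ± 0.61 FPKM (-1.29 ± 0.14, adjusted p = 0.0277).

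Several called genes belong to repeated sequences, and their values are uncertain because reads can be assigned to another copy. HMRA2, the a2 reading frame annotated at a silent mating-type cassette, rose by 1.11 ± 0.09 (limma, adjusted p = 0.0150). A strain of mating type a also carries a2 at its active mating-type locus, so this value cannot be assigned to the silent cassette. Reading frames of Ty retrotransposons moved in both directions. YBR012W-A rose by 1.43 ± 0.19 (adjusted p = 0.0474) and YGR038C-A by 0.69 ± 0.09 (adjusted p = 0.0349), whereas YML045W fell by 0.91 ± 0.09 (adjusted p = 0.0195). The low-abundance Ty frames YOR343W-A, at 5.99 ± 1.56 against 0.315 ± 0.445 FPKM, and YDR210W-B, at 1.65 ± 0.51 against 12.2 ± 1.94 FPKM, were also called and lie outside the naming rule.

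**Figure D1:**
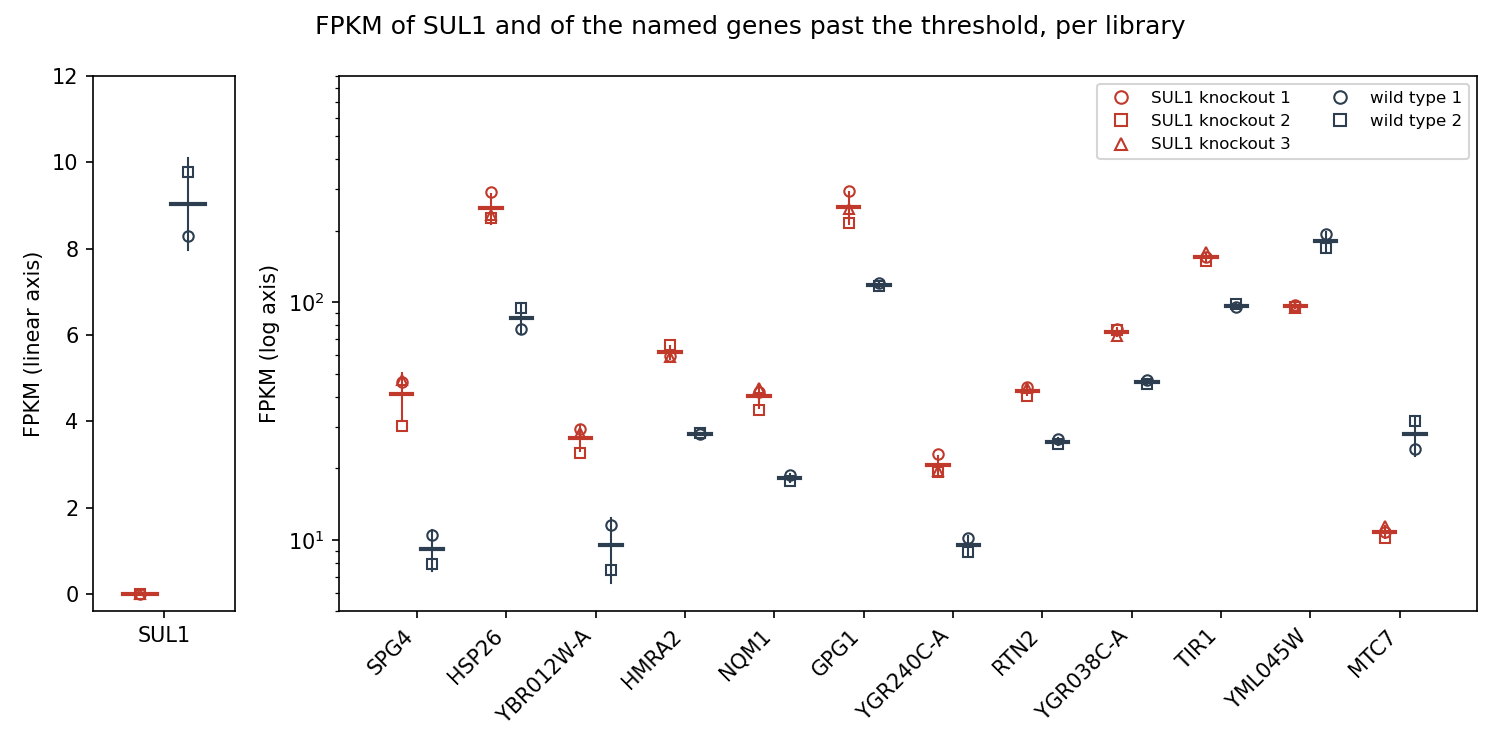
FPKM of SUL1 (linear axis) and of the 12 other genes named by size of change (log axis) in each of the 3 knockout and 2 wild-type libraries; horizontal bars are group means and vertical bars 1 SD. SUL1 sits at 0 in the knockout libraries and at 8.28 and 9.78 FPKM in the wild type, and the groups do not overlap for any gene drawn.

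Of 5712 genes tested, 11 were higher and 4 lower in the knockout at an adjusted p under 0.05 (limma, Benjamini-Hochberg). The split was 4 higher and 4 lower after scaling to equal FPKM sums, and 5 higher and 1 lower after removal of a length trend, with HSP26, NQM1, HMRA2, YGR038C-A and SUL1 among the calls left. At an unadjusted p under 0.05 there were 1060 genes, 395 higher and 665 lower, against 285.6 expected by chance. The libraries of the groups did not overlap for 2347 genes, or 41.1%, where chance gives 20%. Both chance figures are averages, and genes of 1 library share shifts, so a single comparison can lie far from them without an effect of genotype. With the length trend removed, 652 genes had an unadjusted p under 0.05 (limma). The counts of called genes rested on single libraries. Without knockout replicate 2, 298 genes were higher and 598 lower, and all 15 calls remained. Without knockout replicate 1 there were 5 and 4, and without knockout replicate 3 there were 0 and 1 (limma, 623 genes at an unadjusted p under 0.05). Without wild-type replicate 1 or wild-type replicate 2 no gene was called (limma, 747 and 318 genes at an unadjusted p under 0.05), the lone library being assumed to vary like the knockout group.

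The general stress response driven by the transcription factors Msn2 and Msn4, which PKA holds back, had the largest median of the lists on the values as deposited. With equal FPKM sums its median was 0.32, and those of ribosome biogenesis and amino acid biosynthesis, at -0.40 and -0.38, lay farther from 0. The median of all tested genes was itself -0.16 with equal FPKM sums, against -0.07 as deposited. Every list median given here with equal FPKM sums carries this shift, so a change of sign need not be particular to a list. Log2 fold changes were positive for 45 of the 50 stress-response genes, with a median of 0.40. In knockout replicate 2, 31 of the 50 were lower than in both other knockout libraries, with a median difference of -0.21 from their mean. Of these, HSP26, NQM1 and RTN2 rose over all genes tested, and 25 were higher and 0 lower adjusted over the list alone. HSP12, a membrane-protecting stress protein, had 327 ± 79.0 FPKM in the knockout (SD, n = 3) and 114 ± 25.6 in the wild type (SD, n = 2), a log2 fold change of 1.51 ± 0.22 that missed the threshold over all genes (limma, adjusted p = 0.0799). The cytosolic catalase CTT1 had 33.9 ± 6.23 and 22.3 ± 2.26 FPKM (0.57 ± 0.17, adjusted p = 0.182). The list was higher relative to all other genes (camera of limma, adjusted p = 1.75e-22), which was not so with an estimated correlation (adjusted p = 0.393 with an estimated correlation). Its median was 0.46 after removal of the length trend. Without knockout replicate 2, 29 members were called higher, and 27 with the length trend also removed. Without knockout replicate 1 HSP26 alone was called, and without knockout replicate 3 or either wild-type replicate none was (limma, with 623, 747 and 318 genes of all tested at an unadjusted p under 0.05).

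Heat-shock genes of the Hsf1 list were not called with all 5 libraries, and their difference from the stress list was not tested. The median log2 fold change of these 21 chaperone genes was 0.01 and turned negative, at -0.09, with equal FPKM sums, and no member was called over all genes or adjusted over the list alone (camera of limma, adjusted p = 0.388). HSP104, the disaggregase shared by both lists, had 660 ± 277 FPKM in the knockout and 623 ± 317 in the wild type. BTN2 had 858 ± 227 and 1271 ± 13.2 FPKM and MBF1 1845 ± 387 and 1594 ± 124. Levels within the groups were far apart. Of the 21 genes, 19 were lower in knockout replicate 2 than in both other knockout libraries, and 20 were lower in wild-type replicate 1 than in wild-type replicate 2. Without knockout replicate 2 the median was 0.21, 1 member was called higher and 1 lower, and the list was called higher. The list was also called without wild-type replicate 2, a fit that leaves a single wild-type library. With an estimated correlation, run on all 5 libraries only, the list was not called (camera of limma, adjusted p = 0.865).

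Genes of storage carbohydrates and of late growth phases stood higher as lists. Trehalose and glycogen genes had positive values in 18 of 21 cases and a median of 0.22 (camera of limma, adjusted p = 0.000106, and adjusted p = 0.566 with an estimated correlation). None was called over all genes and 2 were higher adjusted over the list alone, namely the glycogen branching enzyme GLC3 (0.68 ± 0.17 SE) and PGM2. TPS1, the trehalose-6-phosphate synthase, had 274 ± 49.7 FPKM in the knockout and 205 ± 13.0 in the wild type, and the glycogen synthases GSY1 and GSY2 had log2 fold changes of 0.41 ± 0.14 and 0.22 ± 0.10, with no call over all genes. Leaving out knockout replicate 2 gave 4 members higher and 1 lower. Stationary-phase markers had a median of 0.31 over 12 genes (camera of limma, adjusted p = 0.000168, and adjusted p = 0.393 with an estimated correlation). SPG4 was called over all genes and 4 markers adjusted over the list alone, and 6 over all genes without knockout replicate 2. Glucose-repressed genes had a smaller median of 0.14 over 30 genes (camera of limma, adjusted p = 0.00115, and adjusted p = 0.566 with an estimated correlation), with 0 calls over all genes and 0 adjusted over the list alone, and 3 higher and 1 lower without knockout replicate 2. Among them CIT2 and MDH2 had 0.57 ± 0.19 and 0.57 ± 0.29. ADH2, the alcohol dehydrogenase of ethanol consumption, chosen after its values were seen, read 21.3 ± 1.95 FPKM in the knockout and 21.5 ± 1.93 in the wild type.

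Ribosome biogenesis genes, which PKA and TORC1 promote in growing cells, were lower in the knockout as a list. Log2 fold changes were negative for 117 of 120 genes, with a median of -0.31 (camera of limma, adjusted p = 5.38e-18, and adjusted p = 0.566 with an estimated correlation). Of the 120, 94 were higher in knockout replicate 2 than in both other knockout libraries, with a median difference of 0.19 from their mean. No member was called over all genes (limma), whereas 46 were lower adjusted over the list alone. UTP20 and RRP5, large scaffold proteins of ribosome precursors, had -0.70 ± 0.27 and -0.63 ± 0.20 (SE). Their median coding length was 1539 bp, and the median of the list after removal of the length trend was -0.21, with 5 of 120 values positive. Without knockout replicate 2, 65 members were called lower, against 4 once the length trend was also removed. Subunits of RNA polymerases I and III had a median of -0.19 over 20 genes (camera of limma, adjusted p = 0.0252, and adjusted p = 0.676 with an estimated correlation). RPA190 and RPA135, the largest subunits of polymerase I, had -0.63 ± 0.24 and -0.51 ± 0.20, with 0 calls over all genes and 0 adjusted over the list alone. In the absence of knockout replicate 2, 4 polymerase genes were called lower. The polymerase list lost its call without knockout replicate 1 and without wild-type replicate 1.

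Translation factors had a median of -0.19 over 37 genes (camera of limma, adjusted p = 3.58e-05, and adjusted p = 0.393 with an estimated correlation). None was called over all genes. Adjusted over the list alone, 6 were lower and 1, the start-site factor SUI1 at 0.33, was higher. The elongation factor YEF3 had -0.38 ± 0.09 (SE) and the initiation scaffold TIF4631 -0.44 ± 0.14. Over all genes, 6 factors were called lower without knockout replicate 2. Cytosolic ribosomal protein genes, in contrast, had a median of 0.09 over 135 genes, which was -0.01 with equal FPKM sums and -0.0003 after removal of the length trend. The list was higher in the camera test (limma, adjusted p = 2.34e-08, and adjusted p = 0.566 with an estimated correlation), and lost the call with the length trend removed, at an adjusted p of 0.635 and the opposite sign. None of its genes was called over all genes and 5 were higher adjusted over the list alone, whereas 7 were higher and 1 lower over all genes without knockout replicate 2. RPS30B and RPS29B, of 192 and 171 coding bp, had the largest values, 1.01 ± 0.20 and 0.82 ± 0.20.

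**Figure D2:**
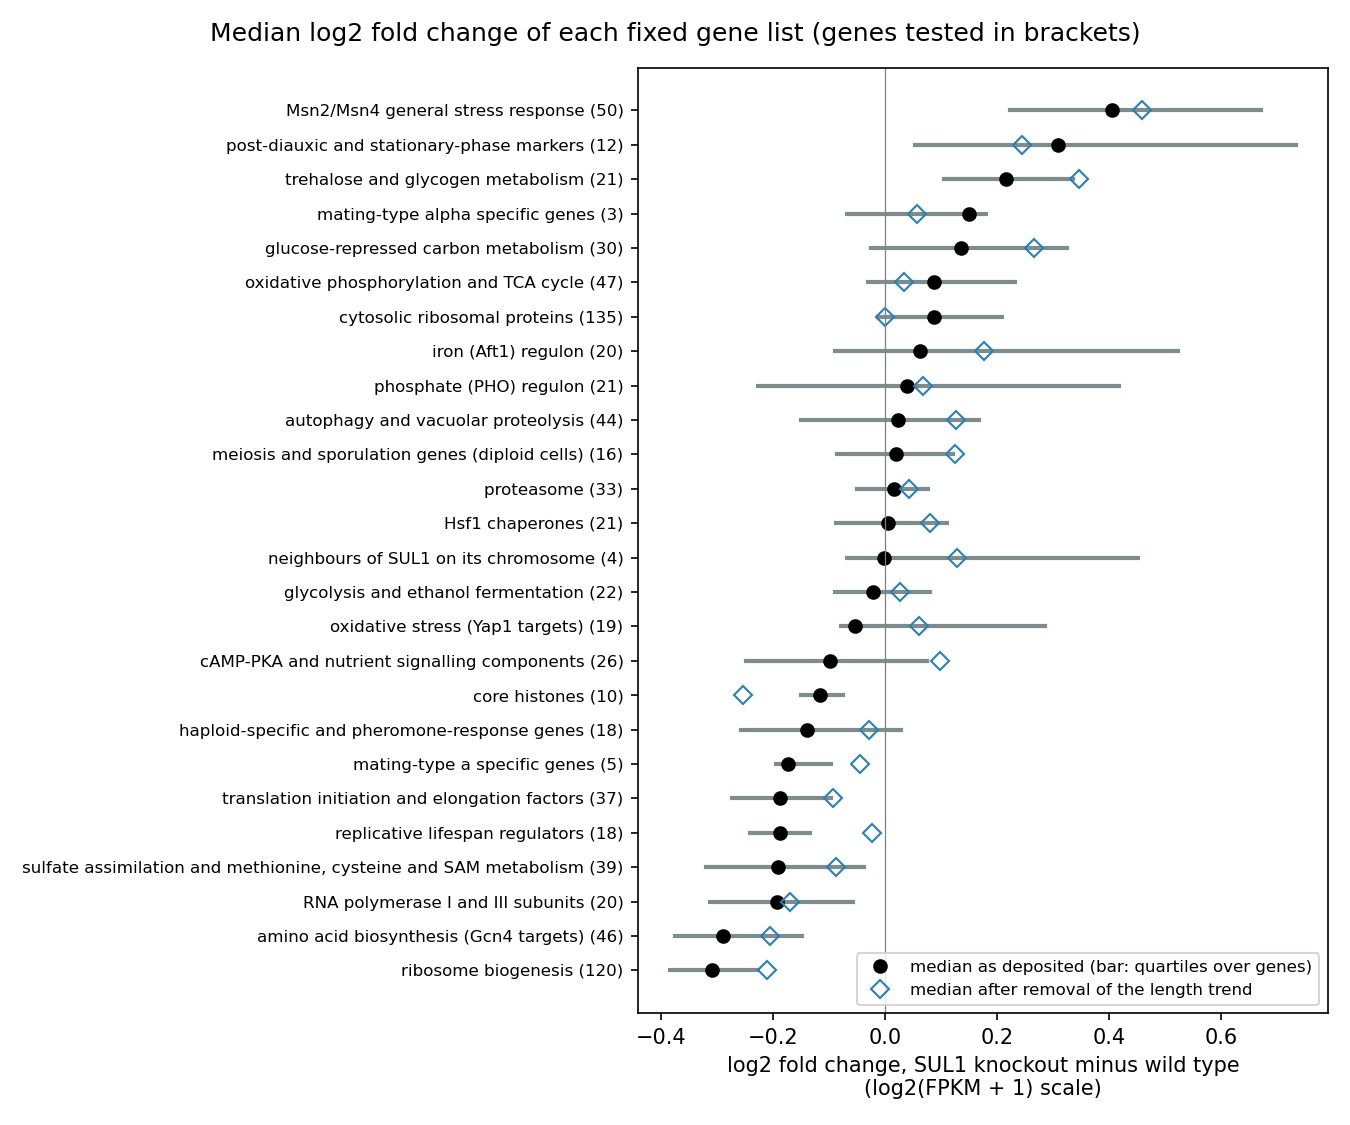
Median log2 fold change (knockout minus wild type, log2(FPKM + 1) scale) of each fixed list with at least 3 tested genes; filled points are medians of the values as deposited, grey bars their quartiles over genes, and open diamonds the medians after removal of the length trend. The stress response has the highest median, 0.40 before and 0.46 after, and ribosome biogenesis the lowest as deposited, at -0.31.

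Genes of amino acid biosynthesis under Gcn4 control were also lower as a list, with negative values in 45 of 46 genes and a median of -0.29 (camera of limma, adjusted p = 5.21e-10, and adjusted p = 0.566 with an estimated correlation). None was called over all genes and 22 were lower adjusted over the list alone. LYS2, of lysine synthesis, had 18.5 ± 2.65 FPKM in the knockout (SD, n = 3) and 30.8 ± 2.41 in the wild type (SD, n = 2). The median was -0.21 after removal of the length trend. Without knockout replicate 2, 11 members were called lower, and 0 once the length trend was also removed (limma, 1478 genes of all tested at an unadjusted p under 0.05).

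Sulfate assimilation and methionine genes had a median of -0.19 over 39 genes (camera of limma, adjusted p = 0.00911, and adjusted p = 0.566 with an estimated correlation). No member was called over all genes, and 3 were lower adjusted over the list alone. These were the adenosylhomocysteine hydrolase SAH1 (-0.37), the methionine synthase MET6 (-0.44) and the S-adenosylmethionine synthetase SAM1 (-0.41), which act downstream of sulfide rather than in sulfate uptake. MET17, which links sulfide to these steps, is lacking in BY4741. Their values therefore cannot be read as a flow of sulfate taken up through SUL1. The methionine permeases MUP1 and MUP3 had the largest values, -0.55 ± 0.38 and -0.58 ± 0.28 (SE), within the spread between replicates. Over all genes, 7 members were called lower without knockout replicate 2. The call of the list was lost without wild-type replicate 1.

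Among its neighbours on chromosome II, PHO89 (796798 to 798522, reverse strand), a sodium-phosphate cotransporter, had 37.7 ± 10.9 FPKM in the knockout (SD, n = 3) and 10.98 ± 2.79 in the wild type (SD, n = 2). Its log2 fold change of 1.68 ± 0.24 (SE) missed the threshold over all genes (limma, adjusted p = 0.0799), and it was the 1 neighbour higher adjusted over the list alone. VBA2, PCA1 and CTP1 had log2 fold changes of -0.13, -0.05 and 0.04. This list of 4 tested genes was not called by camera (limma, adjusted p = 0.216). The phosphate regulon as a list had a median of 0.04, which was -0.05 with equal FPKM sums, and no call (camera of limma, adjusted p = 0.0633), with SPL2 at 0.61 ± 0.21; it was called higher without knockout replicate 1, with equal FPKM sums and after removal of the length trend (adjusted p = 0.0273, and adjusted p = 0.522 with an estimated correlation). Leaving out knockout replicate 2 gave 6 of its genes higher and 4 lower. Adjusted over the list alone 2 of its 21 genes were higher, PHO89 and the vacuolar polyphosphate subunit VTC1.

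No member of the fixed list of PKA pathway components, which does not hold GPG1, was called with all 5 libraries. TPK2 and TPK3 had log2 fold changes of 0.10 ± 0.14 and -0.28 ± 0.13 (SE). The regulatory subunit BCY1 had -0.04 ± 0.13, MSN2 -0.10 ± 0.12 and MSN4 0.24 ± 0.18, and RGS2, a regulator of the glucose-sensing G protein, ranged from 16.1 to 50.1 FPKM within the knockout. The list of 26 components had a median of -0.10 and 0.10 after removal of the length trend, and 0 members called over all genes or adjusted over the list alone (camera of limma, adjusted p = 0.775). With the length trend removed the list was called higher (adjusted p = 0.0471, and adjusted p = 0.522 with an estimated correlation). When knockout replicate 2 was left out, 2 members were called higher and 2 lower. Lifespan regulators had a median of -0.19 over 18 genes with 0 calls on either count (camera of limma, adjusted p = 0.390), and 1 higher and 2 lower without knockout replicate 2. PNC1, the nicotinamidase that raises Sir2 activity, had 1581 ± 367 FPKM against 967 ± 105 (0.68 ± 0.21, adjusted p = 0.198), and HAP4, an activator of respiratory genes, 0.43 ± 0.19.

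Autophagy genes had a median of 0.02, which was -0.06 with equal FPKM sums, and a call (camera of limma, adjusted p = 0.0456, and adjusted p = 0.566 with an estimated correlation) that was lost without knockout replicate 1, knockout replicate 3 or wild-type replicate 1. ATG8, the ubiquitin-like protein of the autophagosome, had 94.0 FPKM in knockout replicate 2 against 179 and 161 in knockout replicates 1 and 3, and 92.6 ± 1.46 in the wild type. ATG41 had 293 FPKM in knockout replicate 2 against 31.4 and 50.7 in the others. Respiration and TCA cycle genes had a median of 0.09, which was -0.01 with equal FPKM sums (camera of limma, adjusted p = 3.58e-05, and adjusted p = 0.566 with an estimated correlation). That call was lost after removal of the length trend, at an adjusted p of 0.192. ATP15 and ACO1 had 0.73 ± 0.13 and 0.51 ± 0.28, and 1 member was higher adjusted over the list alone. Iron regulon genes had a median of 0.06, which was -0.03 with equal FPKM sums (camera of limma, adjusted p = 0.0148, and adjusted p = 0.664 with an estimated correlation), a call lost without knockout replicate 2 and without wild-type replicate 2. HMX1 and FIT2 had 0.82 ± 0.29 and 0.77 ± 0.38, and 1 member was higher adjusted over the list alone. None of these lists had a member called over all genes with all 5 libraries. Autophagy had 5 higher and 2 lower without knockout replicate 2, respiration 7 and 1, and the iron regulon 1 and 4.

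The next lists gave no call by camera on the values as deposited in all 5 libraries, and no member adjusted over the list alone or over all genes. Over all genes but without knockout replicate 2, 2 glycolysis genes, 2 Yap1 targets and 1 proteasome gene were called higher, and 1 Yap1 target and 2 histone genes lower. Glycolysis genes had a median of -0.02 with a test direction of higher (camera of limma, adjusted p = 0.649), with PDC6 and TDH1 at 0.49 ± 0.22 and 0.37 ± 0.26. Yap1 targets had -0.05, likewise with the opposite test direction (adjusted p = 0.132, and adjusted p = 0.664 with an estimated correlation), with OYE3 and AHP1 at 0.46 ± 0.23 and 0.42 ± 0.13. The signs of both medians turned with median-of-ratios scaling, to 0.04 and 0.01. Proteasome genes had 0.02 and -0.08 with equal FPKM sums (adjusted p = 0.0980, and adjusted p = 0.758 with an estimated correlation), with RPN2 and PRE3 at -0.23 and 0.23. At the preset correlation the proteasome list was called without knockout replicate 2 and with median-of-ratios scaling. The Yap1 list was called without wild-type replicate 1, a fit that leaves a single wild-type library. Histone genes had -0.12 (adjusted p = 0.518), with HHO1 and HTB2 at -0.29 and -0.27, and -0.25 after removal of the length trend, when the list was called lower (adjusted p = 0.000953, and adjusted p = 0.522 with an estimated correlation), as it was without wild-type replicate 2.

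Markers of other cell states showed no call. Genes of mating type a had a median of -0.17 over 5 genes (camera of limma, adjusted p = 0.518), with BAR1 and AGA2 at -0.39 ± 0.26 and -0.20 ± 0.14. Genes of mating type alpha had 0.15 over 3 genes (adjusted p = 0.757), and SAG1 and MF(ALPHA)2 lay at 11.6 FPKM or below in every library. Haploid-specific and pheromone genes had -0.14 (adjusted p = 0.775), with PRM1 and STE12 at -0.48 and -0.45. Meiosis genes had 0.02 and -0.07 with equal FPKM sums (adjusted p = 0.352), with DMC1 and SMK1 at 0.38 and -0.38. No member of these 4 lists was called over all genes or adjusted over the list alone with all 5 libraries, and without knockout replicate 2 there were 2 lower haploid-specific genes and 1 lower meiosis gene.

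Fold changes followed gene length. The median log2 fold change went from 0.16 in the tenth of genes with the shortest coding sequences (132 to 432 bp) to -0.26 in the tenth with the longest (2880 to 14733 bp). Across genes, which are not independent replicates, Spearman's rho between log2 fold change and coding length was -0.517. Within libraries, rho between the deviation from the gene mean and length was -0.270, -0.158 and -0.410 in knockout replicates 1, 2 and 3, and 0.287 and 0.528 in wild-type replicates 1 and 2. Knockout replicate 2 also stood apart from its group. Its correlation with wild-type replicate 1 across genes was 0.993, against 0.987 and 0.988 with knockout replicates 1 and 3, which correlated with each other at 0.997.

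**Figure D3:**
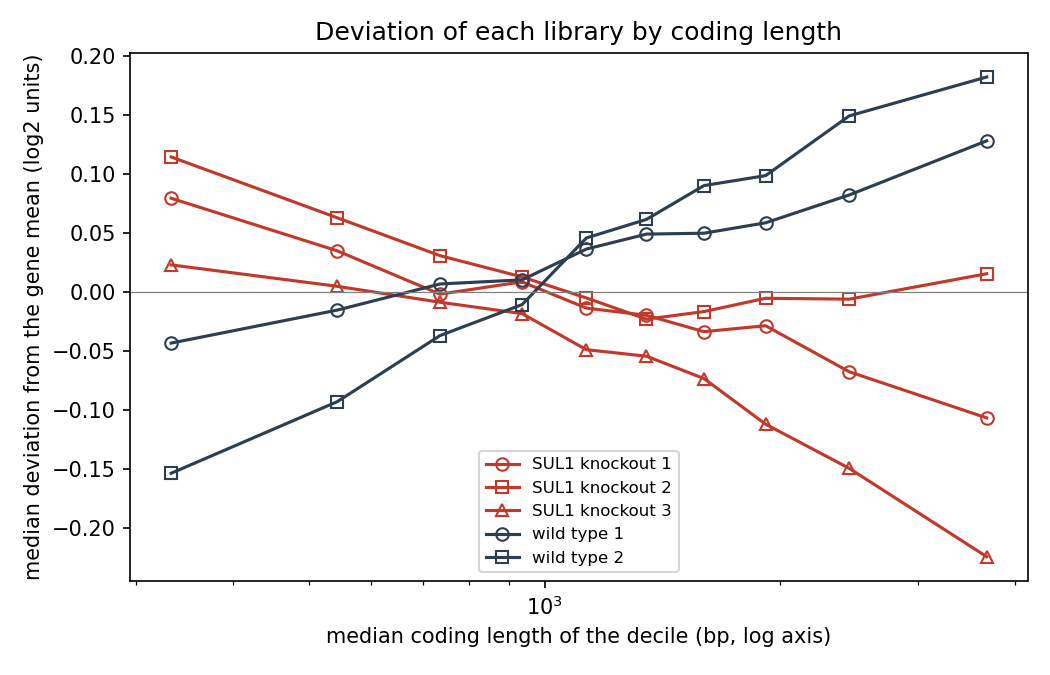
Median deviation of each library from the gene means (log2 units) in 10 bins of genes by coding length (bp, log axis), 1 line per library. Short genes lie above and long genes below in knockout replicates 1 and 3, with medians of -0.11 and -0.22 in the longest bin. In knockout replicate 2 short genes lie above but the longest bin is at 0.02. Both wild-type libraries run the other way, to 0.13 and 0.18.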

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

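The scaling, length, library-weight and combined settings were chosen after the data had been seen; the others were fixed beforehand. No gene called with all 5 libraries reversed under these settings. Of the 13 lists called by camera, 1, the ribosomal proteins, changed direction and lost its call when the length trend was removed. Among the lists not called before, the PKA components turned from lower to higher and were then called (camera of limma, adjusted p = 0.0471, and adjusted p = 0.522 with an estimated correlation). For lifespan regulators and haploid-specific genes only the direction of the camera test turned to higher, without a call. Their medians stayed negative, at -0.02 and -0.03. Leaving out 1 library at a time gave 0 to 298 genes higher and 0 to 598 lower, against 11 and 4 with all 5, and a SUL1 log2 fold change of -3.43 to -3.21, whose size depends on the pseudocount because the knockout is listed at 0. The high counts came without knockout replicate 2. Leaving out any 1 library costs the same degrees of freedom, so that loss does not set the counts of 0 apart from the high counts. Down-weighting libraries that vary more gave 264 higher and 450 lower, with a weight of 0.318 for knockout replicate 2. A mean of at least 10 FPKM left 8 higher and 2 lower, SUL1, YDR210W-B and YOR343W-A being removed by the filter. Equal FPKM sums gave 4 higher and 4 lower. Removal of the length trend gave 5 higher and 1 lower, and 193 and 94 when knockout replicate 2 was also left out. For the weights, the sums, the length trend and knockout replicate 2 the cause was not tested. Median-of-ratios scaling, another pseudocount, no filter and a minimum log2 fold change of 1 gave 8 to 15 higher and 3 or 4 lower.

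With the replicate block, on the 2 numbers that both groups share, 0 genes were higher and 0 lower (limma, 399 genes at an unadjusted p under 0.05) and the SUL1 log2 fold change was -3.32 with an adjusted p of 0.125. With the length trend removed as well, the replicate block gave 0 and 0 (limma, 281 genes at an unadjusted p under 0.05) and -3.17 for SUL1, with an adjusted p of 0.0813. Deviations of same-numbered libraries from their group means correlated at -0.367 and -0.425 across genes, which gives no sign that equal numbers pair the libraries. The deviations of the 2 wild-type libraries are mirror images, so these values are not separate checks.

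Of 13 lists called by camera, 0 were called with an estimated correlation (smallest adjusted p 0.393), and fry called 3, namely translation factors, stationary-phase markers and the neighbours of SUL1, the last carried by PHO89. The other settings called 11 to 14 lists. TMM and library-total scaling, DESeq2, voom and count filters need counts and were not run. Depth limits the lowest genes, 3 fragments on SUL1 being worth 0.0499 to 0.0546 FPKM over the 5 libraries.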

Other observations

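The tests of explanations, the Fisher test and the correlation across genes in this part were chosen after the results had been seen, as were the genes named. Ty retrotransposon reading frames were over-represented among the called genes, with 5 of 15 calls against 69 Ty frames among the 5712 genes tested (Fisher's exact test, two-sided, p = 6.07e-07). That p treats the frames as independent, although near-identical copies share reads. Their log2 fold changes ran from -2.33 to 2.43 with a median of 0.04, and their SD of 0.66 compares with 0.27 for all tested genes. None of the 5 was called without knockout replicate 3, wild-type replicate 1 or wild-type replicate 2, and YBR012W-A, YGR038C-A and YOR343W-A were not called without knockout replicate 1 (limma, with 623, 747, 318 and 628 genes of all tested at an unadjusted p under 0.05). Listed values of single frames moved in opposite directions, such as YOR343W-A, higher, and YDR210W-B, lower. Each of the 5 called frames also overlaps another annotated frame on the same strand over 1317 or 1323 bp. Its value therefore cannot be read as that of a single copy.

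Some genes missed the threshold narrowly. FMP45, a protein of stationary-phase cells, had 7.51 ± 0.61 FPKM in the knockout (SD, n = 3) against 3.02 ± 0.42 in the wild type (SD, n = 2). The aldehyde dehydrogenase ALD3 had 23.8 ± 3.08 against 13.3 ± 0.27, and the cell wall protein SPI1 2107 ± 211 against 1216 ± 169. Lower in the knockout were the helicase DED1, at 69.8 ± 4.64 against 103 ± 4.28, and the cell wall protein TOS1, at 180 ± 16.5 against 272 ± 8.38. The groups' libraries did not overlap for any of these 5, and none passed over all genes (limma, adjusted p of 0.0720 for FMP45 and 0.0799 for the others).

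Within the groups, one set of differences recurred. The heat-shock genes SSA4 and HSP104 had 184 and 340 FPKM in knockout replicate 2 against 493 and 831 in knockout replicate 1, and 230 and 399 in wild-type replicate 1 against 460 and 848 in wild-type replicate 2. ARO9 and ARO10, of aromatic amino acid breakdown, and the cell wall genes CWP1, SED1 and SLT2 followed the same order, while ATG41 and the repressor NRG1 ran opposite to it. Across genes, the difference of knockout replicate 2 from the mean of the other knockout libraries correlated at 0.425 with the difference between wild-type replicates 1 and 2, although these differences share no library. In substance this is the correlation of -0.425 given above for the libraries numbered 2, with its sign turned, and not a further observation.

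Short genes were higher and long genes lower in the knockout as a group, though the longest genes were not lower in knockout replicate 2 (median deviation 0.02). Over the 4889 genes outside every fixed list the log2 fold change fell by 0.111 per doubling of coding length (95% bootstrap interval over genes -0.120 to -0.103), which argues against changes of ribosomal protein genes or other fixed lists as the cause. This slope was 0.965 of that over all genes. Most genes enter both slopes, so the ratio could hardly depart from 1, and it does not test for a length bias that runs through whole libraries. A difference between the strains' cells and one between their libraries cannot be told apart, because the gap between the groups' library slopes was only 1.28 times the largest range within a group and nothing else separates strain from library.

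The stress-response list was higher in the knockout. The length bias is argued against as the cause, since the list's median of 0.40 became 0.46 (95% bootstrap interval over genes 0.36 to 0.54) with the trend removed. Cultures wholly past the diauxic shift are argued against by the small changes of the 30 glucose-repressed genes, with a median of 0.14. Their median differed by -0.27 from that of the stress list (interval -0.54 to -0.12). The stress list was compared after it had shown the highest median as deposited, so this difference by itself decides little. Its interval covers the spread over genes, not over cultures. The difference was -0.42 without knockout replicate 2 and -0.45 without wild-type replicate 2. It was smaller without knockout replicate 1 or 3, at -0.25 and -0.23, and after removal of the length trend, at -0.19 (interval -0.36 to -0.05). Without wild-type replicate 1 it was -0.33. The highest log2 fold change among the glucose-repressed genes was 0.57, or 0.66 with the length trend removed, 0.87 without knockout replicate 2 and 0.88 without wild-type replicate 1. An approach to the shift, and with it a smaller difference in culture density or handling between the groups, cannot be told apart from the genotype: stationary-phase markers did not lie clearly below the stress list (difference -0.10, interval -0.49 to 0.49), NQM1 and SPG4 were called, the glucose-repressed list was itself higher by camera, and only 3 of 5 libraries, all knockout, carry a density in their label. Lower PKA activity in cells without SUL1, which the study proposes, may give the same shift and stays untested.

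Knockout replicate 2 lay closer to wild-type replicate 1 than to the other knockout libraries, 73.7% of the way along the line from their mean to it on the log2 scale. That mean enters both differences, which by itself raises the share, and a share of log2 differences is not a share of cells. An exchange of labels with a wild-type library is argued against by SUL1, listed at 0 FPKM in knockout replicate 2. A share of wild-type cells mixed into the culture would bring 6.10 FPKM of SUL1 if that distance were taken as the share of cells. The figure is rough, but the 0 observed argues against such a mixture as the whole cause. A culture day or batch shared across the groups may link these libraries, and 0 labels name a day or batch, so it cannot be told apart from chance similarity of 2 cultures.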
